A study of Mus musculus with 24 samples.

How the data were processed

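RNA-seq libraries were made with the Illumina TruSeq stranded mRNA kit from macrophages grown out of bone marrow, per the labels' protocols. The authors deposited 1 table of raw read counts per gene and library, with 38293 genes named by Ensembl identifiers and 24 columns. The submitters' processing notes name TopHat2 2.0.11, a read aligner, HTSeq 0.6.1p1, a package with a read counter, and the genome build GRCm38. The strand setting and mode of the counting step and the annotation release are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical gene copies may therefore be assigned differently than assumed, and values of such genes are uncertain. Each column was matched to its sample by title, and each sample to its group, replicate number, animal and batch by the labels. In the table, 16929 genes had no read in any library.

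Coordinates came from the GENCODE M21 annotation of GRCm38 and symbols from it and a table of Ensembl gene names, which matched 36429 identifiers. The other 1864 genes held at most 0.352% of the reads of any library. They stayed in the table and in the tests but were not named. Library totals ran from 10772969 to 17695160 counts, and the 37 mitochondrial genes took 0.88% to 1.516% of them. No pair of replicates was a repeated deposit: over 2000 genes, chi-square per degree of freedom between replicates of a group ran from 26.67 to 363.44. Levels are counts per 1000000 counts of the library (CPM), scaled by TMM factors of 0.944 to 1.054, computed here from the deposited counts. Each library stands for 1 culture, and each animal gave 2 libraries. In the genotype comparisons, p-values measure the spread between animals, since each group holds 1 library per animal. The main test takes the 2 libraries of an animal as independent and estimates the spread from all 24 libraries. It therefore counts more independent samples than the 12 animals, in the genotype comparisons too. The alternative fit of only the groups compared avoids this there. For the IL-4 comparisons and their difference, p-values of the main test also leave out this pairing, which the fit with the animal as a block includes.

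The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3) with robust dispersion, TMM factors, and edgeR's default low-count filter by group, which kept 12049 genes. A single fit held all 24 libraries, with a mean for each of the 4 groups and a batch term. It gave 5 comparisons: IL-4 against control in WT and in KO, KO against WT without and with IL-4, and the difference of the IL-4 responses. Adjusted p are Benjamini-Hochberg values over the genes tested, and genes under 0.05 are called higher or lower. Standard errors are the size of the log2 fold change divided by the square root of its F. The common biological coefficient of variation was 0.154. Fixed gene lists, 27 of them with 475 entries, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists with tested members in each comparison, and again with a correlation estimated from the data. With an estimated correlation, camera kept the calls of alternative activation in both IL-4 comparisons, of amino acid stress, inflammatory activation and cholesterol synthesis in both genotype comparisons, and of fatty acid synthesis in KO against WT with IL-4. It kept no list call of the difference of responses. SREBP components, a list that holds the deleted gene Scap, were called with it in both genotype comparisons, but not without Scap (adjusted p = 0.066 without and 0.24 with IL-4). In the fit of all libraries without the animal, a list's median, mean and test differed in sign only for lists that camera did not call. In batch 2 alone, the median of a called list was 0 for SREBP components in KO against WT without IL-4 and opposite to the test for inflammatory activation in the difference. The entry Ear11 matched no gene of the table.

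The IL-4-responsive genes were chosen on the average response over both genotypes, at an adjusted p under 0.05 and a log2 fold change of at least 1 either way. Their response per animal was the difference of log2 CPM (prior count 2), and genotype was permuted over all 400 arrangements of the animals within batches. Genes within 10 Mb of Lyz2 were compared with the rest by Fisher's exact test. Folds against a group with 1 to 3 reads carry exact 95% counting intervals, and those against 0 reads use a floor of 3 counts over the group. The design, the lists, the alternatives and the naming rule were set before the data were examined. The genes named are Scap, Lyz2, Srebf1 and Srebf2 in every comparison, and up to 4 members of each list with the smallest p. The 8 largest rises and 8 largest falls by fitted log2 fold change are named too, among called genes with a mean of at least 5 CPM, a symbol that is not a clone name, and the same direction in all 6 animals or in both batches. The rule also takes the genes behind any count of 5 or fewer, which for counts within lists was followed only in part, and some genes that the rule selects are not reported here. The genes Avil, Hmga1b, Ch25h, Gja1, Il4ra, Abca1, Havcr2 and Axl were chosen after their values were seen.

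Control and IL-4 cultures of an animal carry the same animal number in the labels. Deviations of these pairs from their group means correlated at 0.37 to 0.69, and at 0.42 to 0.63 once batch was removed, and each of the 12 pairs correlated best with its own partner. The animal was therefore used as a block in an alternative fit for the IL-4 comparisons and their difference. Replicate numbers shared by WT and KO belong to different animals. Other alternatives were DESeq2 1.42.0, limma-voom with the animal as a random block (correlation 0.29), RLE factors, library totals without TMM, no low-count filter, a filter of 1 CPM in at least 12 libraries, no batch term, each batch alone, only the groups compared, an adjusted p under 0.01, a log2 fold change of at least 1, and each animal left out with both its libraries. For the IL-4-responsive genes a log2 fold of at least 2 and a prior count of 0.5 were tried, and for Lyz2 windows of 5 and 20 Mb. Separate group means per batch, counts thinned to the lowest total, and the lists without Lyz2 or Scap were added after seeing the data.

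The fit was tested on simulated counts for the 12049 genes with 200 of them changed. In the WT IL-4 comparison it recovered 87% of genes changed by a log2 fold of 1 and 97% of those changed by 2, and in the KO comparison 79% and 99%. The values were 85% and 97% for KO against WT without IL-4, 81% and 98% with IL-4, and 76% and 92% for the difference of responses. It called 7 to 12 unchanged genes and 0 unchanged lists. The simulated counts had no batch effect, no link between the libraries of an animal and no correlation between genes. They therefore cannot show how the fit and camera behave where these are present, as they are in the real data. Figures were drawn with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.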

Results

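Gene expression was measured by RNA-seq in mouse macrophages grown from bone marrow in medium conditioned by L929 cells, a fibroblast line that supplies macrophage growth factor. Scap encodes the escort protein that carries the SREBP transcription factors out of the endoplasmic reticulum when sterols are low. WT cultures came from mice whose Scap alleles are floxed but that carry no Cre. KO cultures came from floxed mice with 1 Cre allele at the lysozyme locus Lyz2, which deletes Scap in macrophages. Cultures of 6 animals per genotype were left untreated or received interleukin 4 (IL-4), a cytokine that drives alternative activation, at 10 ng/ml for 24 h. Each of the 12 animals gave 1 library without and 1 with IL-4, so the 24 libraries form 4 groups of 6. The labels place 3 animals of each genotype in each of 2 batches. Counts per library ran from 10772969 to 17695160, and the deepest were the KO libraries with IL-4 in batch 2, at 17090995, 17695160 and 17370046.

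Scap levels followed the genotype labels in all 24 libraries. Scap (ENSMUSG00000032485, GRCm38 chromosome 9, 110333288 to 110384950, protein coding) measured 133.7 ± 5.42 counts per 1000000 counts (CPM) in WT without IL-4 and 129.8 ± 7.74 CPM in WT with IL-4 (mean ± SD, n = 6 each). KO cultures measured 35.09 ± 4.84 CPM without and 31.16 ± 4.72 CPM with IL-4 (n = 6 each). The highest KO library, at 42.3 CPM, lay below the lowest WT library, at 121 CPM. Gene counts do not show which exons the remaining reads come from. Lyz2 (chromosome 10, 117277331 to 117282321), the gene carrying the Cre allele, was also lower in KO, at a log2 fold change of −1.29 ± 0.17 without IL-4 and −0.87 ± 0.17 with IL-4 (± SE throughout, edgeR adjusted p = 2.4e-05 and 0.00041). Y-linked genes were detected in every library. Xist measured at most 0.167 CPM in any of them.

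**Figure D1:**
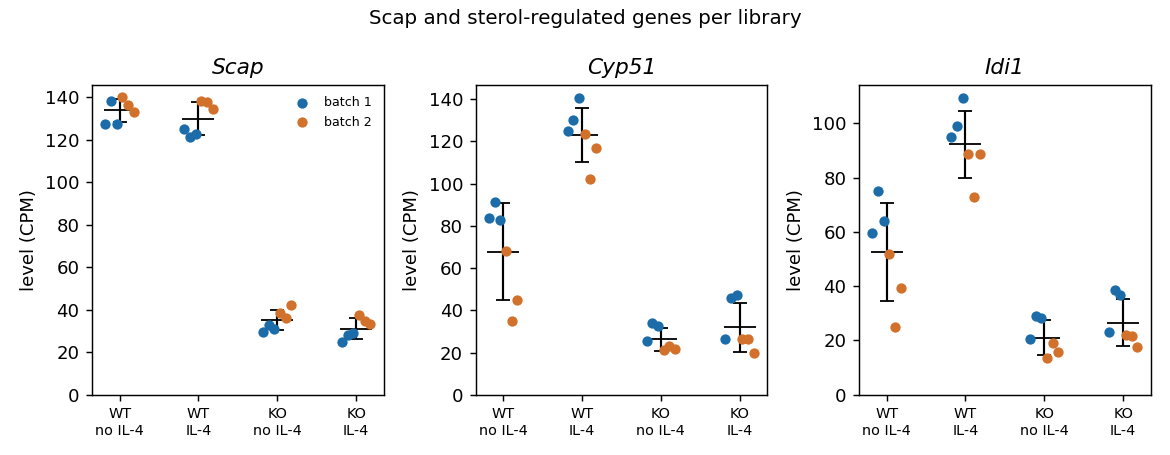
Levels of Scap, Cyp51 and Idi1 (CPM, linear axes from 0) in each library, by group on the horizontal axis; points are libraries, coloured by batch, and black marks give the mean and SD of 6 libraries. Scap lies between 24.7 and 42.3 CPM in the KO libraries and between 121 and 140 CPM in the WT libraries.

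The first comparison asked how WT macrophages respond to IL-4. The list of alternative activation genes rose as a group, with 25 of 29 tested members higher and 2 lower (25 and 3 adjusted over the list alone; median log2 fold change 4.21, camera adjusted p = 4.4e-43, and adjusted p = 1.1e-08 with an estimated correlation). Retnla, a secreted resistin-like protein, went from 4.11 ± 0.855 to 10000 ± 2810 CPM (n = 6 animals), a log2 rise of 11.21 ± 0.30. Pdcd1lg2, a ligand of the PD-1 receptor, rose by 8.88 ± 0.36, Flt1, a VEGF receptor, by 8.34 ± 0.33, and Socs1, a suppressor of cytokine signalling, by 6.28 ± 0.23. Beyond this list, the ribonuclease gene Rnase2a rose from 0.17 ± 0.0758 to 410.8 ± 250 CPM, the sodium channel gene Scn3a by 10.58 ± 0.42 and Tmem26 by 9.23 ± 0.30. Among genes with a mean of at least 5 CPM, the 8 largest falls included Cx3cr1, the fractalkine receptor (−5.45 ± 0.51), and the paired immunoglobulin-like receptor genes Pilrb2 (−5.02 ± 0.32) and Pilra (−4.94 ± 0.29). The other 5 were Itga8, Siglece, Bank1, Fcrl1 and Sncaip, whose log2 changes ran from −4.96 to −4.33. Each of these genes moved the same way in all 6 WT animals, and the edgeR adjusted p was 2.6e-07 or lower for every one. Some genes had few or no reads without IL-4. The potassium channel gene Kcnd3 had 0 reads over the 6 control libraries, which makes it at least 357-fold higher with IL-4, against a floor of 3 counts over the group. Msx3 had 2 reads (1980-fold, 95% exact counting interval 548 to 16400), Cldn11 1 read (2470-fold, 442 to 97500) and the chitinase-like gene Chil4 1 read (761-fold, 136 to 30100). Intervals and floors cover counting error only, and levels of Chil4, Rnase2a, Pilra and Pilrb2 are uncertain where reads could be shared with similar genes of their families.

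Metabolic and secretory gene lists also rose in WT with IL-4. Cholesterol synthesis genes were higher in 22 of 23 tested members, and in 23 adjusted over the list alone (median 0.648, camera adjusted p = 2.6e-06, adjusted p = 0.44 with an estimated correlation), among them Acat2 (0.96 ± 0.13) and the sterol dehydrogenase gene Nsdhl (0.78 ± 0.12). Their median was 0.47 in batch 1 and 0.943 in batch 2. Subunits of oxidative phosphorylation rose in 23 of 25 members (median 0.42, camera adjusted p = 1.3e-09, adjusted p = 0.2 with an estimated correlation) with the same count adjusted over the list alone. So did tricarboxylic acid cycle enzymes in 17 of 20 (0.391, 2.4e-06, and 0.2 with an estimated correlation; 17 over the list alone). Cyc1, a cytochrome subunit, rose by 0.84 ± 0.07 and the malate dehydrogenase Mdh2 by 0.69 ± 0.08. Fatty acid oxidation genes rose in 14 of 20 members (median 0.305, camera adjusted p = 0.0014, adjusted p = 0.37 with an estimated correlation), including the coactivator Ppargc1b (2.53 ± 0.20). Unfolded protein response genes rose in 15 of 18 members and fell in 1 (16 and 1 adjusted over the list alone; median 0.781, camera adjusted p = 2.7e-10, adjusted p = 0.25 with an estimated correlation). Among them were the chaperones Pdia4 (1.99 ± 0.13) and Calr (1.15 ± 0.08). All 7 tested genes of the dendritic cell list rose (median 2.20, camera adjusted p = 0.0015, adjusted p = 0.39 with an estimated correlation and 0.011 with the animal as a block as well). Of the 15 listed genes only these 7 had enough counts to be tested: H2-Aa, H2-Ab1, H2-Eb1, Cd74 (3.33 ± 0.39), Ciita (2.93 ± 0.48), Batf3 and Zbtb46. All but Batf3 and Zbtb46 are genes of antigen presentation that activated macrophages also express. Batf3 is also in the alternative activation list.

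Interferon response and macrophage identity genes fell in WT with IL-4. Of the interferon list 15 of 22 members fell and 0 rose (18 and 0 adjusted over the list alone; median −1.223, camera adjusted p = 0.0015, adjusted p = 0.69 with an estimated correlation). Ifit3 measured −3.67 ± 0.55 and the chemokine Cxcl10 −3.64 ± 0.54. Of the macrophage identity list 11 of 16 members fell and 1 rose, with the same counts adjusted over the list alone (median −0.434, camera adjusted p = 0.001, adjusted p = 0.34 with an estimated correlation). The endotoxin coreceptor Cd14 fell by 3.22 ± 0.22 and Lyz2 by 1.94 ± 0.17, and without Lyz2 the list median was −0.42 (camera adjusted p = 0.0045). Several lists missed the threshold in the fit without the animal and passed it with the animal as a block. They were inflammatory activation (3 higher, 7 lower of 17; 0.063 and, blocked, 0.037), antioxidant and glutathione genes (6 higher, 15 lower of 30; 0.063 and 0.037), amino acid stress (9 higher, 2 lower of 18; 0.067 and 0.018) and lysosome (10 higher, 2 lower of 24; 0.063 and 0.032). The multinucleation and osteoclast list (5 higher, 3 lower of 8; 0.33 and 0.0031) and the T and B lymphocyte list (0 higher, 3 lower of 3, which are Cd4, Cd79b and Ighm; 0.13 and 0.0037) did so too. None of these 6 blocked calls held with an estimated correlation, where the blocked adjusted p ran from 0.13 to 0.5. Amino acid stress measured a median of 0.494 in batch 1 (camera adjusted p = 0.31) and 1.189 in batch 2 (8.8e-05). Inflammatory activation was called in both batches alone (−0.483, 0.0036 and −0.529, 0.037), antioxidant genes in batch 1 (−0.295, 0.016, against −0.067, 0.14) and T and B lymphocyte markers in batch 2 (−1.439, 0.044, against −1.329, 0.29). Within these lists Tnf fell by 2.64 ± 0.24, the inflammasome sensor gene Nlrp3 by 2.19 ± 0.12, glutathione reductase Gsr by 1.15 ± 0.10 and the ferritin heavy chain Fth1 by 0.98 ± 0.10. The costimulatory receptor Cd40 rose by 1.98 ± 0.21.

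No call in WT was made by camera for fatty acid synthesis (9 higher, 3 lower of 19; adjusted p = 0.28, and 0.043 in batch 2 alone), SREBP pathway components (2 higher, 1 lower of 7; 0.75) or LXR target genes (4 higher, 5 lower of 12; 0.61). The same held for the pentose phosphate list (9 higher, 4 lower of 16; 0.31), glycolysis (6 higher, 5 lower of 20; 0.68, and 0.037 in batch 2 alone), lipid uptake (6 higher, 3 lower of 20; 0.49) or cell cycle (1 higher of 24, Pcna; 0.91). Nor was one made for neutrophil markers (2 lower of 8, Camp and Mmp8; 0.61), fibroblast markers (0 of 7 called; 0.89) or sex-linked genes (1 higher of 4, Eif2s3y; 0.68). No gene of the mast cell and basophil list or of the erythroid list had enough counts to be tested. Across all 12049 tested genes, 2923 were higher and 2819 lower with IL-4 in WT (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 599 and 702 of these changed at least 2-fold. Batch 1 alone gave 1858 and 1799 genes and batch 2 alone 2597 and 2375, with a correlation of 0.91 between their fold changes across genes.

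The second comparison asked the same of KO macrophages. Alternative activation genes rose here too, with 26 of 29 members higher and 1 lower, the same counts adjusted over the list alone (median 3.73, camera adjusted p = 1.2e-45, adjusted p = 5.3e-09 with an estimated correlation). Retnla went from 3.68 ± 0.628 to 3568 ± 1580 CPM (n = 6 animals; log2 rise 9.84 ± 0.29) and the arginase gene Arg1 from 3.77 ± 3.14 to 1923 ± 342 CPM (9.14 ± 0.54). Scn3a rose by 10.32 ± 0.44, Rnase2a by 9.89 ± 0.42 and the cadherin gene Cdh1 by 7.08 ± 0.29. The cytokine receptor gene Il31ra had 0 reads in the 6 KO control libraries and was at least 198-fold higher with IL-4, against the same floor. Kcnd3 had 1 control read (1860-fold, 95% exact counting interval 333 to 73400) and Chil4 1 (1550-fold, 278 to 61200). Large falls were found in Pilra (−5.46 ± 0.28), Cx3cr1 (−5.29 ± 0.50) and Sncaip (−5.14 ± 0.31).

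Cholesterol synthesis genes were higher in 6 of 23 members in KO with IL-4, and in 5 adjusted over the list alone. The list itself was not called (median 0.265, camera adjusted p = 0.19), and its median was 0.226 in batch 1 and 0.155 in batch 2. Unfolded protein response genes rose in 17 of 18 members (median 0.556, camera adjusted p = 0.00013, adjusted p = 0.57 with an estimated correlation). So did oxidative phosphorylation subunits in 17 of 25 (0.193, 0.0013, and 0.57 with an estimated correlation) and tricarboxylic acid cycle enzymes in 13 of 20 (0.244, 0.011, and 0.57 with an estimated correlation). Adjusted over the list alone these counts were 17, 20 and 13. Lysosomal genes rose in 11 of 24 members and fell in 3 (median 0.267, camera adjusted p = 0.0058, adjusted p = 0.71 with an estimated correlation), with the protease gene Ctsz at 1.07 ± 0.07. Interferon genes fell in 15 of 22 members (median −1.197, camera adjusted p = 0.0013, adjusted p = 0.71 with an estimated correlation). Macrophage identity genes fell in 12 of 16, with 1 higher (median −0.541, camera adjusted p = 0.0014, adjusted p = 0.57 with an estimated correlation). Antioxidant and glutathione genes fell in 17 of 30 members and rose in 5 (18 and 5 adjusted over the list alone; median −0.383, camera adjusted p = 0.0014, adjusted p = 0.57 with an estimated correlation). Among them were Gsr (−1.19 ± 0.09), Gclm (−1.09 ± 0.13) and the peroxiredoxin Prdx1 (−1.04 ± 0.11). Cell cycle genes fell in 12 of 24 members (median −0.532, camera adjusted p = 0.016, adjusted p = 0.73 with an estimated correlation), with medians of −0.264 in batch 1 (adjusted p = 0.053) and −0.857 in batch 2 (0.0016). The tricarboxylic acid cycle list was not called in batch 2 alone (0.245, adjusted p = 0.057). The dendritic cell list rose in 5 of 7 members (median 1.75, camera adjusted p = 0.011, adjusted p = 0.57 with an estimated correlation).

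In the same fit 2968 genes were higher and 2853 lower with IL-4 in KO (edgeR adjusted p under 0.05), and 566 and 703 of them changed at least 2-fold. Batch 1 gave 1556 and 1436 and batch 2 gave 2761 and 2657, and the fold changes of the batches correlated at 0.88 across genes. With the animal as a block, camera also called amino acid stress (adjusted p = 0.053 and, blocked, 0.0096), the multinucleation and osteoclast list (0.33 and 0.0089) and the T and B lymphocyte list (0.14 and 0.0089). With an estimated correlation these blocked calls were lost (adjusted p = 0.53, 0.33 and 0.27). Batch 2 alone called amino acid stress (median 0.827, adjusted p = 6.6e-04), and batch 1 did not (0.446, 0.16). Over all libraries camera did not call inflammatory genes in KO (7 higher, 6 lower of 17; median 0.091, adjusted p = 0.26). Nor did it call fatty acid oxidation (9 higher, 1 lower of 20; 0.151, 0.06). Batch 1 alone called inflammatory genes lower (median −0.445, adjusted p = 0.0036, against 0.237 in batch 2) and fatty acid oxidation higher (0.287, 0.0036, against 0.081). Responses in WT and KO, which share no libraries, correlated across the 12049 genes at Pearson r = 0.917 and Spearman rho = 0.812, with a slope of KO on WT of 0.88. Genes are not independent replicates, so no p is given for these values. Of the genes raised in WT, 2189 were also raised in KO, against 720 for independent lists, and 2076 fell in both, against 667. The genes Hlcs, Mms22l and Ubac1 were raised in WT and lowered in KO, and 9 lowered in WT were raised in KO.

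The third comparison set untreated KO macrophages against untreated WT and asked what the loss of Scap changes at rest. Every tested cholesterol synthesis gene was lower in KO, 23 of 23, also adjusted over the list alone (median −0.92, camera adjusted p = 6.6e-33, adjusted p = 0.014 with an estimated correlation). They included the sterol demethylase gene Cyp51 (−1.34 ± 0.16) and Idi1 (−1.31 ± 0.16). Batch medians of this list were −1.062 and −0.741. Fatty acid synthesis genes were lower in 11 of 19 members, 13 adjusted over the list alone (median −0.324, camera adjusted p = 3.3e-07, adjusted p = 0.066 with an estimated correlation). They included the desaturase Fads2 (−1.19 ± 0.25) and the synthase Fasn (−0.86 ± 0.19). That median was −0.564 in batch 1 and −0.168 in batch 2, where camera gave an adjusted p of 0.055. Srebf2, which encodes the SREBP that favours cholesterol genes, went from 244.9 ± 47.6 to 130.5 ± 17.4 CPM (−0.90 ± 0.11), and Srebf1 measured −0.35 ± 0.13 without passing the threshold (edgeR adjusted p = 0.074). SREBP pathway components were lower in 3 of 7 members, 4 adjusted over the list alone (camera adjusted p = 2e-13). Without Scap the median was −0.17 and the camera adjusted p 0.0077, and with an estimated correlation that call was lost (adjusted p = 0.066). LXR target genes, which serve cholesterol export, were lower in 6 of 12 members, 8 adjusted over the list alone (median −0.605, camera adjusted p = 3.7e-06, adjusted p = 0.066 with an estimated correlation). The LXR medians were −0.724 in batch 1 and −0.23 in batch 2, and those of the SREBP components −0.67 and 0. Among the LXR targets the apolipoprotein gene Apoe went from 2600 ± 1090 to 646.8 ± 296 CPM (−2.01 ± 0.32) and the lipid transfer protein gene Pltp was also lower (−1.28 ± 0.16).

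Amino acid stress, inflammatory, unfolded protein response and glycolysis genes were higher in untreated KO macrophages. Amino acid stress genes were higher in 15 of 18 members, 17 adjusted over the list alone (median 1.101, camera adjusted p = 9.7e-21, adjusted p = 0.011 with an estimated correlation). The pseudokinase gene Trib3 went from 4.46 ± 2.26 to 76.98 ± 54 CPM (3.80 ± 0.53). The mitochondrial folate enzyme Aldh1l2 (3.08 ± 0.39), the glutathione-degrading enzyme Chac1 (2.99 ± 0.44) and the serine synthesis enzyme Phgdh (2.51 ± 0.25) were higher as well. The list median was 0.742 in batch 1 and 1.515 in batch 2. Inflammatory activation genes were higher in 9 of 17 members, 10 adjusted over the list alone, and 0 were lower (median 0.827, camera adjusted p = 2.7e-07, adjusted p = 0.011 with an estimated correlation). The acute phase gene Saa3 was higher by 3.23 ± 0.46 and the chemokine Ccl3 by 0.83 ± 0.13. The chemokine Cxcl3 had 106 reads against 2 in WT (48.2-fold, 95% exact counting interval 13 to 403) and the cytokine gene Il6 66 against 2 (30-fold, 7.99 to 253), both near the detection limit. Untreated KO libraries measured 0.707 to 2.22 CPM of Il6 in batch 2 and at most 0.0637 CPM in batch 1, a spread that the counting interval leaves out. Unfolded protein response genes were higher in 12 of 18 members, 14 adjusted over the list alone (median 0.409, camera adjusted p = 5.7e-13, adjusted p = 0.078 with an estimated correlation), including the chaperone Hspa5 (0.80 ± 0.12). Glycolysis genes were higher in 8 of 20 members, 11 adjusted over the list alone (median 0.305, camera adjusted p = 2.1e-06, adjusted p = 0.27 with an estimated correlation). Antioxidant genes were higher in 8 of 30 members and lower in 1 (9 and 1 adjusted over the list alone; median 0.117, camera adjusted p = 0.0092, adjusted p = 0.42 with an estimated correlation), among them the cystine transporter Slc7a11 (1.87 ± 0.48). Batch 1 alone gave a median of 0.037 with an adjusted p of 0.3. Interferon genes were called as a list with 2 of 22 members higher (median 0.384, camera adjusted p = 0.0038, adjusted p = 0.69 with an estimated correlation), at medians of 0.818 in batch 1 and 0.069 in batch 2, where camera gave an adjusted p of 0.55.

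Macrophage identity genes were lower in 8 of 16 members in untreated KO, 10 adjusted over the list alone (median −0.354, camera adjusted p = 2.4e-06, adjusted p = 0.066 with an estimated correlation; −0.31 and 6.6e-05 without Lyz2). They included the growth factor receptor gene Csf1r (−0.51 ± 0.10) and Adgre1, which encodes F4/80 (−0.61 ± 0.11). Among genes with a mean of at least 5 CPM, the largest rises elsewhere were in coagulation factor F5 (4.81 ± 0.62), Cox6a2 (4.08 ± 0.64), the iron-binding protein gene Lcn2 (3.66 ± 0.61), the short-chain fatty acid receptor Ffar2 (3.40 ± 0.67) and the aquaporin Aqp9 (3.32 ± 0.56). The growth factor gene Csf1 went from 8.79 ± 1.27 to 93.05 ± 48.8 CPM (3.27 ± 0.31). The largest falls of such genes besides Apoe and Scap were in the cell fusion gene Dcstamp (−2.77 ± 0.67), Adam19 (−2.42 ± 0.31), the prostaglandin-degrading enzyme Hpgd (−2.29 ± 0.43), Ighm (−2.24 ± 0.38), the MHC class II transactivator Ciita (−2.08 ± 0.59) and Abca9 (−2.01 ± 0.20). Among markers of other cell types, fibroblast markers had 0 of 7 called (camera adjusted p = 0.23) and dendritic cell markers 2 lower of 7, Cd74 and Ciita (0.11). Batch 2 alone called the dendritic cell list lower (median −1.558, adjusted p = 0.041), and batch 1 did not (−0.414, 0.6). Neutrophil markers had 0 of 8 called (median 0.46, 0.23), but camera called the list higher in batch 1 alone (0.856, adjusted p = 0.0072) and not in batch 2 (0.25, 0.81). T and B lymphocyte markers had 1 lower of 3, Ighm (0.048, 0.24 with an estimated correlation, and 0.16 in batch 2 alone), and sex-linked genes 1 lower of 4, Kdm5d (0.23). Alternative activation genes had 4 higher and 4 lower of 29 (camera adjusted p = 0.61) and cell cycle genes 0 of 24 called (0.96). No call was made for the pentose phosphate list (3 higher, 3 lower of 16; 0.69), fatty acid oxidation (1 higher, 1 lower of 20; 0.23) or the tricarboxylic acid cycle (2 higher, 1 lower of 20; 0.23). None was made for oxidative phosphorylation (1 higher of 25; 0.23), lipid uptake (5 lower of 20; 0.13), lysosome (4 higher, 1 lower of 24; 0.56) or multinucleation genes (1 higher, 3 lower of 8; 0.47).

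Across all tested genes 1049 were higher and 1036 lower in untreated KO (edgeR adjusted p under 0.05), and 229 and 74 differed at least 2-fold. Scaling by library totals alone changed this split to 1585 higher and 644 lower, or 71.1% higher in place of 50.3%. Leaving out the animal of KO replicate 5 lowered the count of higher genes to 691. Batch 1 gave 102 and 149 genes and batch 2 gave 1006 and 747, with a correlation of 0.59 between the fold changes. Within 10 Mb of Lyz2, 16 of 68 tested genes were called, or 23.5%, against 17.3% of 11980 genes elsewhere (odds ratio 1.47, 95% interval 0.78 to 2.63, Fisher's exact test, 2-sided, p = 0.2).

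**Figure D2:**
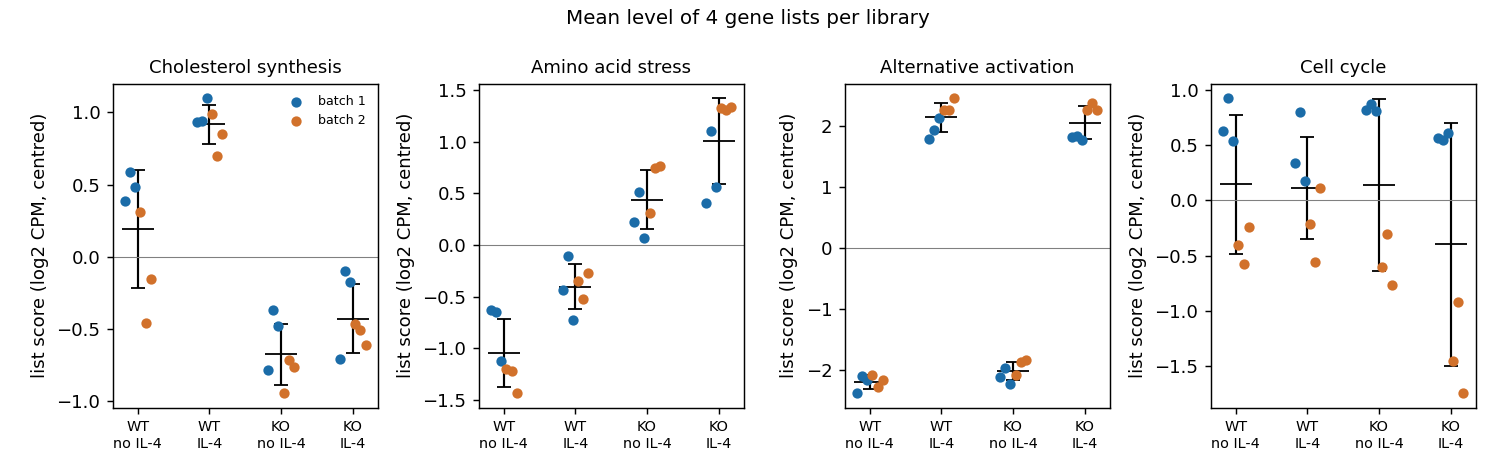
Mean level of 4 gene lists in each library, as the mean over the list's tested genes of log2 CPM after each gene was centred on its mean over the 24 libraries (vertical axes, log2 units); points are libraries coloured by batch, and black marks give the mean and SD of 6 libraries. Cholesterol synthesis scores average 0.92 in WT with IL-4 and −0.43 in KO with IL-4, and the cell cycle scores separate by batch in each group, by most in KO with IL-4.

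The fourth comparison set KO against WT after IL-4. Cholesterol synthesis genes were again lower in 23 of 23 members, also adjusted over the list alone (median −1.384, camera adjusted p = 3.7e-50, adjusted p = 0.0039 with an estimated correlation), with batch medians of −1.406 and −1.359. Examples are Cyp51 (−1.99 ± 0.16), Idi1 (−1.83 ± 0.16) and Acat2 (−1.47 ± 0.13). Fatty acid synthesis genes were lower in 12 of 19 members on both adjustments (median −0.588, camera adjusted p = 1.3e-08, adjusted p = 0.045 with an estimated correlation), with Fads2 at −1.95 ± 0.26 and the citrate lyase Acly at −0.59 ± 0.05. SREBP pathway components were lower in 4 of 7 members and higher in 1 (camera adjusted p = 1.3e-08; without Scap 0.06), and both Srebf2 (−0.99 ± 0.11) and Srebf1 (−0.47 ± 0.13) were lower. LXR target genes were lower in 7 of 12 members, 8 adjusted over the list alone with 1 higher (median −0.473, camera adjusted p = 0.00022, adjusted p = 0.23 with an estimated correlation), at medians of −0.713 in batch 1 and −0.251 in batch 2. Apoe went from 1007 ± 374 to 185.5 ± 50.9 CPM (−2.42 ± 0.32).

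Alternative activation genes were mixed after IL-4: 8 of 29 members were lower in KO and 4 higher, with the same counts adjusted over the list alone, and the list was not called (median −0.003, camera adjusted p = 0.5). Retnla (−1.53 ± 0.19) and the amino acid oxidase gene Il4i1 (−2.27 ± 0.21) were lower (Il4i1 at 38.96 ± 18.8 and 7.57 ± 1.46 CPM in WT and KO). The transglutaminase Tgm2 (1.36 ± 0.16) and the interleukin 1 receptor antagonist Il1rn (1.46 ± 0.24) were higher. Antioxidant genes had 5 members higher and 5 lower of 30 (median 0.011, camera adjusted p = 0.91). Amino acid stress genes were higher in 16 of 18 members, 17 adjusted over the list alone (median 1.311, camera adjusted p = 1.8e-13, adjusted p = 0.045 with an estimated correlation), with Trib3 at 157.6 ± 117 against 8.54 ± 2.45 CPM. Inflammatory genes were higher in 10 of 17 members on both adjustments (median 0.883, camera adjusted p = 2.7e-07, adjusted p = 0.0097 with an estimated correlation). Il6 measured 8.81 ± 8.97 CPM against 0.101 ± 0.0753 CPM (6.24 ± 0.49). In KO it lay between 0.416 and 1.48 CPM in batch 1 and between 14.25 and 20.03 CPM in batch 2. The chemokine Cxcl2 was higher by 3.88 ± 0.53, the costimulatory ligand Cd86 by 2.48 ± 0.34 and Socs3 by 2.42 ± 0.32. Among genes with a mean of at least 5 CPM, the largest other rises were in Ffar2 (4.75 ± 0.54), F5 (4.54 ± 0.59), Aqp9 (4.51 ± 0.54), Sh2d6 (4.28 ± 0.65), the C-type lectin Clec4n (4.13 ± 0.54) and the cholesterol hydroxylase Ch25h (3.77 ± 0.69). The largest falls of such genes besides Apoe and Il4i1 were in Ciita (−2.55 ± 0.47), Abca9 (−2.51 ± 0.22), Zfyve28 (−2.41 ± 0.35), Hpgd (−2.41 ± 0.55), Dcstamp (−2.22 ± 0.48) and Gprc5c (−2.18 ± 0.41).

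Mitochondrial, dendritic cell marker and cell cycle lists were lower in KO after IL-4. Oxidative phosphorylation subunits were lower in 11 of 25 members with 1 higher (14 and 1 adjusted over the list alone; median −0.132, camera adjusted p = 0.0012, adjusted p = 0.42 with an estimated correlation). Fatty acid oxidation genes were lower in 11 of 20 with 1 higher (12 and 1 over the list alone; −0.225, 0.0012, and 0.26 with an estimated correlation). Tricarboxylic acid cycle enzymes were lower in 8 of 20 members (median −0.098, camera adjusted p = 0.016, adjusted p = 0.42 with an estimated correlation). Pentose phosphate and NADPH genes were lower in 5 of 16 with 1 higher (−0.181, 0.04, and 0.25 with an estimated correlation), including G6pdx (−0.51 ± 0.10). Tested genes of the dendritic cell list were lower in 6 of 7 (median −1.767, camera adjusted p = 0.0099, adjusted p = 0.42 with an estimated correlation), with Cd74 at 505.7 ± 102 against 1822 ± 1150 CPM. Only 7 of the 15 genes of this list were tested, and most of them are genes of antigen presentation that activated macrophages also express. In batch 1 alone camera lost oxidative phosphorylation (median −0.071, adjusted p = 0.099), fatty acid oxidation (−0.099, 0.065), the tricarboxylic acid cycle (−0.043, 0.14) and dendritic cell markers (−1.139, 0.066). Pentose phosphate genes were called in neither batch alone (0.094 and 0.082). Macrophage identity genes were lower in 9 of 16 members with 1 higher (median −0.368, camera adjusted p = 0.0012, adjusted p = 0.25 with an estimated correlation), including the complement genes C1qb (−0.87 ± 0.13) and C1qc (−0.79 ± 0.15). Cell cycle genes were lower in 10 of 24 members, 12 adjusted over the list alone (median −0.513, camera adjusted p = 0.00017, adjusted p = 0.56 with an estimated correlation). The median was 0.11 in batch 1 (adjusted p = 0.13) and −1.216 in batch 2 (2.2e-09). Camera called none of interferon (0 of 22; adjusted p = 0.052), glycolysis (5 higher, 2 lower of 20; 0.23), lipid uptake (3 higher, 5 lower of 20; 0.42) or unfolded protein response (4 higher of 18; 0.11). Nor did it call lysosome (8 higher, 5 lower of 24; 0.088), multinucleation (1 higher, 3 lower of 8; 0.5), T and B lymphocyte (1 lower of 3, Ighm; 0.15), fibroblast (0 of 7; 0.74) or sex-linked genes (1 lower of 4, Kdm5d; 0.75). Neutrophil markers were not called either (0 of 8; 0.36). Batch 1 alone called higher interferon (median 0.89, adjusted p = 1.7e-07), glycolysis (0.174, 0.0017), neutrophil (0.701, 0.032) and lysosome genes (0.079, 0.046), which batch 2 did not (−0.16, −0.062, 0.145 and 0.148). Batch 2 alone called the unfolded protein response higher (0.33, 0.00024), at −0.069 in batch 1.

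In all, 1876 genes were higher and 2084 lower in KO with IL-4 (edgeR adjusted p under 0.05), and 321 and 208 differed at least 2-fold. The batches differed here: batch 1 gave 272 and 257 genes and batch 2 gave 2364 and 2288, and the KO against WT difference itself changed between the batches in 1514 genes. Scaling by library totals gave 2288 higher and 1530 lower, 59.9% higher in place of 47.4%. Of the genes higher in KO without IL-4, 677 were also higher with IL-4, against 163 for independent lists, and 665 were lower in both, against 179. These comparisons draw on the same animals, which adds to such overlaps. Fold changes without IL-4 in batch 1 and with IL-4 in batch 2, from different animals, correlated at 0.43 across genes, and the opposite pairing at 0.53.

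The fifth comparison tested whether the IL-4 response itself differed between the genotypes. Retnla rose less in KO, by a difference of −1.38 ± 0.33 (edgeR adjusted p = 0.049). The mannose receptor gene Mrc1 rose more, by 0.74 ± 0.18 (0.048), from 2562 ± 223 to 7094 ± 1660 CPM in KO and from 3582 ± 407 to 5923 ± 828 CPM in WT (n = 6 each). With IL-4 it measured 5360 to 6142 CPM in KO and 5903 to 7051 CPM in WT in batch 1. In batch 2 it measured 7550 to 9778 CPM in KO and 5013 to 5871 CPM in WT. The stress-induced gene Gadd45a measured 9.01 ± 2.81 without and 4.48 ± 1.55 CPM with IL-4 in WT, which passed the threshold only with the animal as a block (edgeR adjusted p = 0.071 and, blocked, 9.3e-04). In KO it rose from 18.87 ± 12.7 to 64.91 ± 57.1 CPM, a difference of 2.57 ± 0.55 (0.036). KO libraries with IL-4 measured 12.81 to 23.71 CPM of Gadd45a in batch 1 and 82.13 to 152 CPM in batch 2. The collagenase gene Mmp13 reached 55.56 ± 14.2 CPM in WT and 658.1 ± 638 CPM in KO (difference 2.17 ± 0.49, 0.044). Its KO libraries with IL-4 measured 130.2 to 250.5 CPM in batch 1, and 678.1, 822.7 and 1834 CPM in batch 2. Jcad (difference 1.73 ± 0.41) and the integrin gene Itgb3 (1.60 ± 0.35) also rose more in KO. Socs3 fell in WT and rose in KO (2.06 ± 0.43). Tox2 fell in WT and did not pass the threshold in KO (1.78 ± 0.37), and Sh3pxd2a (1.35 ± 0.30) and Cyfip2 (1.33 ± 0.19) fell less in KO than in WT. Tarm1 (−2.86 ± 0.49) and the transcription factor gene Nfil3 (−1.16 ± 0.17) rose less in KO. Ccdc69 (−1.11 ± 0.22), Lbh (−1.10 ± 0.24), Pde8b (−0.82 ± 0.17) and the sterol synthesis gene Nsdhl (−0.73 ± 0.17) rose in WT and did not pass the threshold in KO. The kinase gene Fgr fell in KO and did not pass the threshold in WT (−1.30 ± 0.28). For Tarm1, levels with IL-4 were 44.4 ± 8.29 CPM in WT and 47.05 ± 7.73 CPM in KO, and levels without IL-4 were 0.54 ± 0.288 and 4.45 ± 3.30 CPM. Every named difference had the same sign in both batches. The naming rule required this of all these genes but Mrc1, so it is no separate support.

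Cholesterol synthesis genes responded less to IL-4 in KO as a list (median difference −0.448, camera adjusted p = 2.3e-12, adjusted p = 0.27 with an estimated correlation), with 1 of 23 members called, Nsdhl, and 14 adjusted over the list alone. Batch medians were −0.272 and −0.655. Oxidative phosphorylation subunits (median −0.178, camera adjusted p = 7.2e-09, adjusted p = 0.22 with an estimated correlation; 0 of 25 called, 12 adjusted over the list alone) also responded less. So did tricarboxylic acid cycle enzymes (−0.17, 2.4e-06, and 0.22 with an estimated correlation; 2 of 20 called, 5 over the list alone), among them Cs (−0.34 ± 0.07). Unfolded protein response genes did so with 3 of 18 members called, 8 over the list alone (median −0.361, camera adjusted p = 2.7e-07, adjusted p = 0.44 with an estimated correlation), which are Pdia3, Creld2 and Calr (−0.61 ± 0.11). Batch 2 alone did not call this list (−0.348, adjusted p = 0.17). Cell cycle genes had 0 of 24 members called on either adjustment (median −0.439, camera adjusted p = 2.7e-07, adjusted p = 0.56 with an estimated correlation), at −0.003 in batch 1 and −1.021 in batch 2. Negative list differences were also called for pentose phosphate and NADPH genes (−0.258, 0.0013), glycolysis (−0.283, 0.0022), fatty acid oxidation (−0.126, 0.0051), antioxidant genes (−0.168, 0.0073) and fatty acid synthesis (−0.152, 0.039). None of these 5 had a member called over all genes, and over the list alone they had 1, 3, 1, 5 and 1. With an estimated correlation their adjusted p were 0.22, 0.6, 0.53, 0.56 and 0.6. Batch 1 alone gave adjusted p of 0.033, 0.47, 0.75, 0.96 and 0.25 for them. The dendritic cell list was called only with the animal as a block (median −0.774, camera adjusted p = 0.11 and, blocked, 2.8e-05), and not with a block and an estimated correlation (adjusted p = 0.12). The remaining lists, alternative activation included (median −0.347, camera adjusted p = 0.22), were not called, with adjusted p from 0.12 to 0.95. In batch 2 alone camera called inflammatory activation higher (adjusted p = 0.02) while its median was −0.007.

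In total 56 genes had a more positive and 40 a more negative IL-4 response in KO (edgeR adjusted p under 0.05), out of 1797 with an unadjusted p under 0.05. With the animal as a block the counts were 322 and 337, and all 96 genes remained among them. Leaving out 1 animal took them as low as 12 (without WT replicate 5) and 9 (without WT replicate 4 or 6), and dropping the batch term gave 9 and 4. Batch 1 alone gave 0 genes by edgeR. There 490 of 12017 genes had an unadjusted p under 0.05, no more than that threshold gives by chance. Batch 2 alone gave 431 and 419. Among 573 genes raised by IL-4 on average over both genotypes, the median response was 1.64 in WT and 1.59 in KO. The median difference of KO minus WT was −0.111, with 57.4% of the genes responding less in KO (exact permutation test over 400 arrangements of the animals within batches, 2-sided, p = 0.01), at −0.113 in batch 1 and −0.132 in batch 2. It lost the threshold without the animal of KO replicate 1 (exact permutation p = 0.15), KO replicate 2 (0.105), KO replicate 3 (0.13), WT replicate 4 (0.07) or WT replicate 6 (0.43). For 704 lowered genes the median difference was 0.009 (exact permutation p = 0.88), at 0.099 in batch 1 and −0.114 in batch 2.

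**Figure D3:**
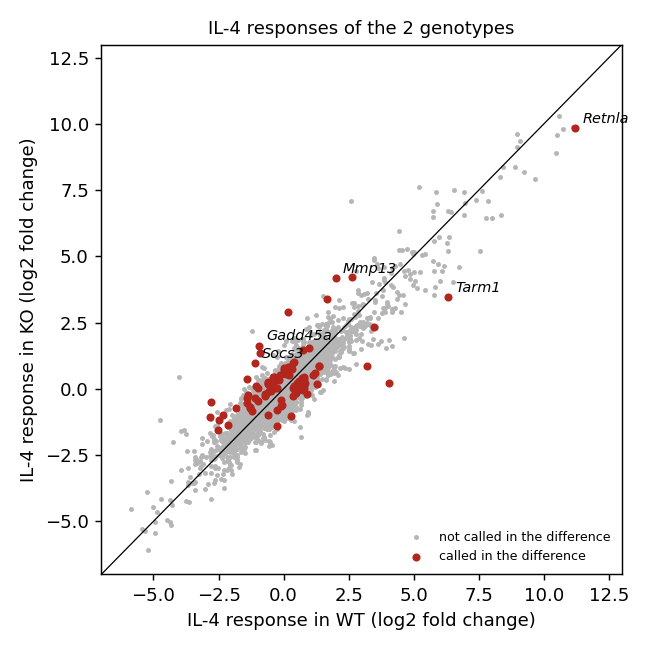
IL-4 response of each of 12049 tested genes in WT (horizontal axis) and KO (vertical axis), as log2 fold changes, with the line of equal response; red points are the 96 genes whose response differed between genotypes. Retnla and Tarm1 lie below the line, and Mmp13, Gadd45a and Socs3 above it.

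**Figure D4:**
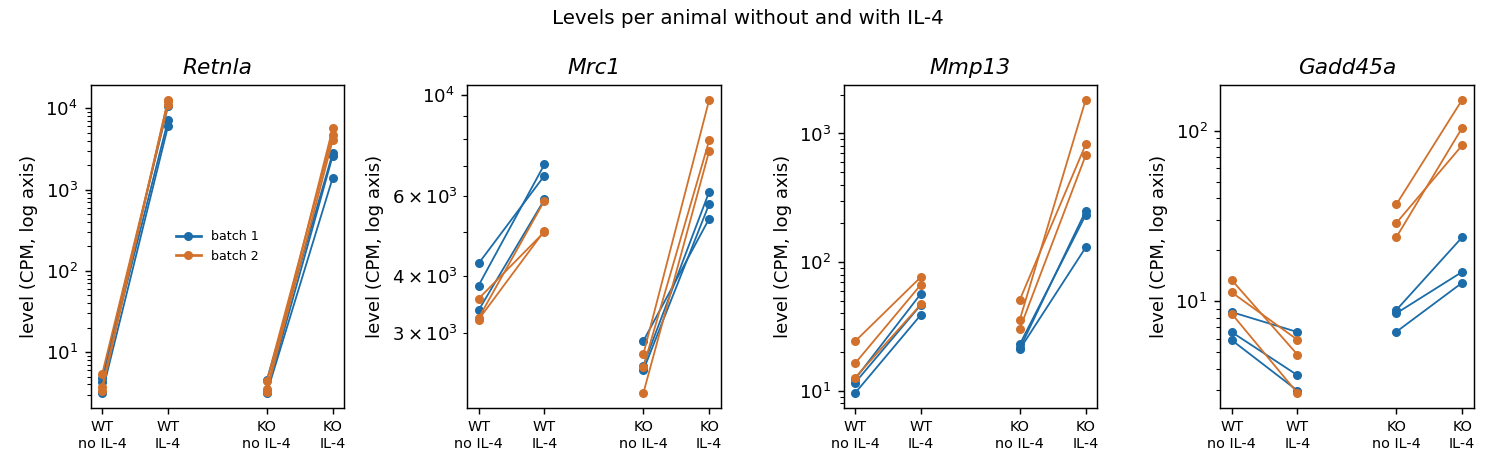
Levels of Retnla, Mrc1, Mmp13 and Gadd45a (CPM, logarithmic axes) without and with IL-4; each line joins the libraries of 1 animal, coloured by batch. Gadd45a is lower with IL-4 in each WT animal and higher in each KO animal.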

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

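The tests of neutrophil markers, of the Cre allele, of chromosome segments, and of the batch dependence with its thinned counts were chosen only after the results were seen. Among 152 sets of 6 libraries, 4 had a library set apart from the other 5 by Dixon's ratio, and chance marks about 1 in 20. Kcnd3 measured 0.0679 CPM in KO control replicate 5 and 0 in the others. Scn3a measured 0 in WT control replicate 5 and 0.073 to 0.0894 CPM in the others. Both genes lie at the detection limit without IL-4. Cox6a2 measured 1.98 CPM in WT control replicate 5 against 0.146 to 0.703 CPM. Tarm1 measured 60.3 CPM in WT IL-4 replicate 6 against 37.8 to 45.4 CPM.

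The IL-4 response differed between the genotypes in 96 genes by the test of the difference itself, 56 with a more positive and 40 with a more negative response in KO. The difference of KO minus WT, on the log2 scale, was positive for Gadd45a (2.57), Mmp13 (2.17), Socs3 (2.06), Tox2 (1.78), Jcad (1.73), Itgb3 (1.60), Sh3pxd2a (1.35) and Cyfip2 (1.33). It was negative for Tarm1 (−2.86), Retnla (−1.38), Fgr (−1.30), Nfil3 (−1.16), Ccdc69 (−1.11), Lbh (−1.10), Pde8b (−0.82) and Nsdhl (−0.73). Camera found more negative responses in KO, as list medians, for cholesterol synthesis (−0.448), cell cycle (−0.439), the unfolded protein response (−0.361), glycolysis (−0.283) and the pentose phosphate list (−0.258). Smaller ones were found for oxidative phosphorylation (−0.178), the tricarboxylic acid cycle (−0.17), antioxidant genes (−0.168), fatty acid synthesis (−0.152) and fatty acid oxidation (−0.126). None of these list calls held with an estimated correlation. For single genes, batch 1 alone gave 0 calls of the difference by edgeR (490 of 12017 at an unadjusted p under 0.05). Batch 2 alone gave 431 more positive and 419 more negative.

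Other splits of the same libraries argue against chance as the source of the gene counts in each comparison. Of 100 splits, 1, the real one, reached the real count. That share is the smallest that 100 splits can give. Splits that mix the groups also widen the spread within groups, which lowers their counts. The IL-4 comparison called 5742 genes in WT, and the highest other split called 3306. In KO these values were 5821 and 3001. Among the 32 splits that part each animal's libraries as the real one does, the highest others were 2622 and 2879. The remaining splits put both libraries of at least 1 animal on the same side. KO against WT called 2085 genes without IL-4 (highest other 493) and 3960 with IL-4 (highest other 2568). The difference of responses called 96 genes, and every other split drawn called 0 by edgeR. Their unadjusted counts were not recorded, and no other tool was run on the splits, so how near they came to a call is not known.

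The difference between KO and WT with IL-4 itself differed between the batches in 1514 genes, 683 with a higher and 831 with a lower value in batch 2. With all libraries thinned to the lowest total 1347 genes still differed, which argues against depth as the cause. Leaving out KO IL-4 replicate 4, 5 or 6 gave 1096, 1612 and 853 genes, which argues against a single library as the cause. Neighbouring genes were called in the same direction in 149 pairs, 1.56 times as often as at shuffled positions (78 to 115 pairs), which segments of another strain would give, but as many IL-4 response genes gave a ratio of 2.62, so co-regulated neighbours give it as well. Without IL-4, the KO against WT difference changed between the batches in few genes, 7 with a higher and 1 with a lower value in batch 2. The test of whether this batch dependence itself changed with IL-4 also called few genes, 7 and 1. A gene not called without IL-4 can still differ there, so these counts cannot decide about segments of another strain. Such segments stay open. So do a difference between the KO animals of the batches and a difference in culture, which were not tested.

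Inflammatory genes were higher in untreated KO cultures, and neutrophils in the cultures could contribute. The summed level of S100a8 and S100a9, abundant neutrophil transcripts, was 9.56 ± 4.94 CPM in WT and 15.2 ± 6.58 CPM in KO (n = 6 each), a rise of 5.64 ± 3.36 CPM (SE). Lcn2, which is not in the inflammatory list, rose by 34 ± 16.9 CPM and Saa3 by 20.7 ± 8.71 CPM, errors too wide to decide. Of 11 neutrophil genes listed these cultures express 8, of which edgeR called 0, and the labels name no sort or gate. Camera called the neutrophil list higher in batch 1 alone (median 0.856, adjusted p = 0.0072) and not in batch 2 (0.25, 0.81). Inflammatory genes were called higher by camera in both batches (0.523, 3.5e-08 and 0.748, 1.0e-06). An effect of the Cre allele or of the lost Lyz2 copy cannot be told apart from the loss of Scap, because 0 groups carry Cre with intact Scap, and the loss of Scap stays open.

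Genes called in untreated KO around Lyz2 could come from DNA of another strain that travels with the Cre allele. The odds ratio of a call within 10 Mb was 1.47 (95% interval 0.78 to 2.63, Fisher's exact p = 0.2), and it was 1.12 within 5 Mb and 1.17 within 20 Mb. The interval holds both no excess and a more than 2-fold one, so 68 genes are too few to decide. Avil, within 10 Mb of Lyz2, had 0 reads in 5 of 6 untreated WT libraries and reads in each KO library. An effect of Scap on these genes stays open as well.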

How the results depend on the processing

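The fit with separate group means per batch, the thinned counts, and the lists without Lyz2 or Scap were chosen only after the data were seen. Under the alternatives, counts of called genes stayed within 1.5 times of the reported count in 205 values, were higher by more than that in 11 and lower in 52. Lists and other tested values that answer a comparison kept their direction and side of the threshold in 514 values, newly passed it in 11, lost it in 21 and reversed in 1. Single genes and other lists did so in 15501, 359, 615 and 2. Depth limits the genes near 1 CPM and the folds against 3 or fewer reads. Unless a cause is given, the cause was not tested.

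At an adjusted p under 0.01, a stricter threshold, the counts higher and lower were 4 and 1 for the difference of responses, 1169 and 1184 for KO against WT with IL-4, and 463 and 473 without. At a log2 fold change of at least 1 they were 16 and 9 for the difference, 566 and 703 for IL-4 in KO, 599 and 702 in WT, 321 and 208 for KO against WT with IL-4, and 229 and 74 without. Batch 1 alone, with 12 of the 24 libraries, gave 0 and 0 for the difference by edgeR (490 of 12017 unadjusted; no other tool was run on it), 1556 and 1436 for IL-4 in KO, 1858 and 1799 in WT, 272 and 257 for KO against WT with IL-4, and 102 and 149 without. There the antioxidant list measured 0.022 for the difference, a reversal (adjusted p = 0.96), −0.295 for IL-4 in WT (called, 0.016) and 0.037 for KO against WT without IL-4 (0.3). Fatty acid synthesis measured −0.066 for the difference (0.25). Batch 1 also reversed cell cycle in KO against WT with IL-4 (0.11, adjusted p = 0.13) and Hspa5 there (−0.02, 0.95). Batch 2 alone gave 431 and 419 for the difference, and fatty acid synthesis measured 0.348 for IL-4 in WT (called, 0.043) and −0.168 for KO against WT without IL-4 (0.055).

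An estimated correlation ended, with unchanged medians, the calls for the difference of antioxidant genes (−0.168, adjusted p = 0.56), cholesterol synthesis (−0.448, 0.27) and fatty acid synthesis (−0.152, 0.6). It also ended antioxidant genes with IL-4 in KO (−0.383, 0.57), cholesterol synthesis with IL-4 in WT (0.648, 0.44), and antioxidant genes (0.117, 0.42) and fatty acid synthesis (−0.324, 0.066) in KO against WT without IL-4. For the difference, DESeq2 gave 195 and 180 genes (fatty acid synthesis −0.153, 0.064), limma-voom 320 and 298, separate means per batch 271 and 290, no batch term 9 and 4, and no low-count filter 21 and 15. Without the batch term KO against WT gave 1230 and 1090 with IL-4 and 461 and 423 without. Library totals alone gave 1585 and 644 for KO against WT without IL-4. The stricter low-count filter put fatty acid synthesis at −0.129 for the difference (0.051). No low-count filter called cholesterol synthesis with IL-4 in KO (0.285, 0.019). Antioxidant genes with IL-4 in WT were called without the filter (−0.21, 0.016), with the stricter one (−0.256, 0.036), with only the groups compared (−0.254, 0.026) and with separate means per batch (−0.222).

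With the animal as a block, the pairing gave 322 and 337 genes for the difference and called antioxidant genes with IL-4 in WT (−0.228, 0.037). It changed no other gene count by more than 1.5 times, and no list call in the IL-4 comparisons and their difference other than those given beside the results. Replicate numbers shared by WT and KO belong to different animals. Their deviations correlated at −0.18 to 0.19 within batches, and 5 of 12 same-numbered pairs correlated best with their own number. As a block these numbers gave 1116 and 1095 genes without IL-4 and 1933 and 2095 with IL-4. They also called dendritic cell markers without IL-4 (0.036), and interferon genes (0.01) and T and B lymphocyte markers (0.041) with IL-4, none of which held with an estimated correlation (0.52, 0.71 and 0.13).

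Leaving out 1 animal gave 12 to 71 higher and 9 to 48 lower genes for the difference, and it leaves fewer samples. The higher and lower counts were 29 and 21 without KO replicate 2, 17 and 12 without KO 4, 13 and 10 without KO 5, 15 and 10 without KO 6, 14 and 9 without WT 4, 12 and 10 without WT 5, and 15 and 9 without WT 6. Lower genes numbered 20 without KO 1 and higher genes 34 without WT 1. KO against WT without IL-4 had 691 to 1207 higher genes, the lowest without KO 5. Fatty acid synthesis in the difference ran from −0.192 to −0.101 and lost its call without KO 2 (0.057), KO 3 (0.094), WT 5 (0.08) or WT 6 (0.16). Antioxidant genes with IL-4 in WT ran from −0.236 to −0.143 and were called without KO 3 (0.048), WT 4 (0.048) or WT 6 (0.035). The difference over IL-4-raised genes ran from −0.169 to −0.039 and lost its call without KO 1 (−0.073), KO 2 (−0.082), KO 3 (−0.07), WT 4 (−0.102) or WT 6 (−0.039). With genes raised at least 4-fold it was −0.274 (exact permutation p = 0.005).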

Other observations

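The genes and tests described here were chosen only after their values were seen. With IL-4, the KO against WT difference changed between the batches in several gene groups, given here as batch 2 minus batch 1. Cell cycle genes were lower in batch 2 in 20 of 24 members (median −1.34, camera adjusted p = 1.9e-19, adjusted p = 0.49 with an estimated correlation). Unfolded protein response genes were higher in 9 of 18 members (0.38, 3.1e-08, and 0.49 with an estimated correlation). Amino acid stress genes were higher in 3 of 18 members (0.57, 0.0074, and 0.63 with an estimated correlation), Trib3 among them (2.25). The interferon list was lower with 0 of 22 members called by edgeR (−1.31, 0.0086, and 0.63 with an estimated correlation). Fatty acid oxidation genes were lower in 5 of 20 members (−0.2, 0.0084) and oxidative phosphorylation subunits in 2 of 25 (−0.18, 0.018), both at an adjusted p of 0.63 with an estimated correlation. Single genes with a higher KO against WT difference in batch 2 include the cholesterol hydroxylase Ch25h (4.43), the gap junction gene Gja1 (3.98), coagulation factor F5 (3.79), the IL-4 receptor gene Il4ra (2.60) and the cholesterol exporter Abca1 (2.30). Lower ones include the checkpoint receptor Havcr2 (−2.72) and the receptor kinase Axl (−2.22). Without IL-4, batch 1 and batch 2 medians of KO against WT also stood apart for amino acid stress (0.742 and 1.515) and interferon genes (0.818 and 0.069). They were 0.307 and 0.518 for the unfolded protein response and 0.087 and −0.087 for cell cycle. Fatty acid oxidation measured −0.082 and −0.046, and oxidative phosphorylation 0.038 and 0.034. The batch split was thus not confined to IL-4 in every list.

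Hmga1b (chromosome 11, 120762794 to 120764419) measured at most 0.296 CPM in the 6 KO libraries of batch 2 and 4.14 to 26.4 CPM in the other 18 libraries. No other gene was off in 1 genotype of 1 batch and on elsewhere by the same rule. Hmga1b is a near-identical copy of Hmga1, so its counts are uncertain.

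Avil, an actin-binding gene (chromosome 10, 127000709 to 127020994), measured 0 CPM in 5 untreated WT libraries and 0.0859 CPM in the other. It had 1 read over the untreated WT libraries and 301 over the untreated KO libraries (274-fold, 95% exact counting interval 48.8 to 10900). In untreated KO it measured 0.133 to 1.27 CPM in batch 1 and 4.15 to 8.97 CPM in batch 2. In KO with IL-4 it measured 0.277 to 2.22 CPM in batch 1 and 10.2 to 12.7 CPM in batch 2. The counting interval leaves out the spread between batches. Avil overlaps the gene Tsfm (127011572 to 127030840), so its counts are uncertain.

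Some smaller responses to IL-4 in KO went with a higher level before IL-4. Nfil3 measured 9.58 ± 1.36 CPM in untreated WT and 21.45 ± 7.94 CPM in untreated KO, and 108.4 ± 24.4 and 107.8 ± 36.2 CPM with IL-4 (n = 6 each). The same was seen for Tarm1, whose levels with IL-4 were 44.4 ± 8.29 CPM in WT and 47.05 ± 7.73 CPM in KO.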
